A study of Mus musculus with 14 samples.

How the data were processed

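MERFISH, an imaging method that counts single RNA molecules of chosen genes inside cells, had been run per the labels on a MERSCOPE instrument on sagittal cryosections of fresh-frozen mouse hemibrains, with cells outlined by a custom Cellpose pipeline. The deposited table held raw counts, as whole numbers of transcripts per segmented cell, with no normalization by the authors, and a deposited cell table gave the sample, imaging run, class, Leiden cluster, total counts and volume of each cell. The volume had no stated unit. Software versions, the gene panel, the filters on cells and the way the classes were assigned were not given in the sources used here. The count table used here held 13602 cells and 255 genes in alphabetical order from Abi3 to Kcnj8, so genes later in the alphabet, Ntrk2 among them, were not analysed here. These genes made up 55.9% to 59.2% of each sample's deposited total counts. Of the 255 symbols, 254 matched a reference gene table of assembly GRCm38.p6, which was used for names only. Unused per-sample columns numbered 0.

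Samples were grouped by their labels into Ctl-Veh (unirradiated, vehicle), Ctl-Rz (unirradiated, RZ), Ir-Veh (irradiated, vehicle) and Ir-Rz (irradiated, RZ). RZ is the abbreviation of the labels, which is kept as written. The labels do not state that samples came from separate animals, so p-values measure only the spread between these samples, which may be technical. Cells were never treated as replicates. No doublet caller was run, because the cells were outlined on images, and no cell was removed, so that 6 cells with under 20 counts were kept.

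Counts were summed per sample, over all cells and within each annotated class with 20 or more cells in the sample. Gene tests used edgeR 4.0.16 (quasi-likelihood fit, TMM factors, filterByExpr) in R 4.3.3, with all 14 samples in 1 fit on group alone. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05. Levels are edgeR's CPM on the TMM-scaled total, as mean ± SD, and log2 fold changes are given ± SE. TMM factors ran from 0.864 to 1.24. Gene lists with 5 or more measured members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), with an estimated correlation and fry beside it. Of 26 lists, 7 reached that size: activated microglia, complement, immediate early genes, inflammatory signalling, inhibitory neuron markers, neurodegeneration-linked genes, and synapse and neurotransmission. Shares of cells and medians per cell were compared by two-sided exact permutation tests over samples. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

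The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. That rule named, for each comparison, Bdnf, Ntrk2, Gfap, Dcx and Arc where measured, up to 10 called genes in each direction, the 2 members with the smallest adjusted p of each list that passed, up to 3 called genes per class and direction, and, where fewer than 10 genes passed, the 10 genes with the smallest p, given as values. Genes named outside the rule were chosen after their values were seen. The alternatives were DESeq2 1.42.0, library size alone, the number of cells as the library size, no filter on low genes, cells with 20 or more counts, 50 or more cells per class, the compared groups alone, the imaging run as a block, and leaving out each sample in turn. Chosen after the data had been seen were the run as a random effect (limma voom with duplicateCorrelation), deposited totals as the library size, genes with 0.2 or more counts per cell (94 genes, with 161 below), leaving out run 9, leaving out the smaller clusters, and list tests within each class with their repeats under the block and without each sample. The comparison of Arc-rich cells between groups and that of cells holding any Arc were chosen later as well.

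The number in each sample title was the number of its imaging run in the cell table, and each of the 7 runs held 2 samples of different groups. After subtraction of group means, samples of the same run deviated together across the 255 genes, with a correlation of 0.298 to 0.671 in the 7 runs, so the numbers paired the samples. Samples of the same group did not share molecules, as the chi-square per degree of freedom between them was 32.5 to 125.

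Total counts per sample ran from 137786 to 434127. The precision this gave was tested on simulated data for the 255 genes, with 50 genes changed and noise shared within runs as fitted here. At that setting edgeR recovered 8.24% of 1.5-fold, 62.9% of 2-fold and 99.4% of 4-fold changes between Ir-Veh and Ctl-Veh. For Ir-Rz against Ir-Veh it recovered 2.35%, 26.5% and 93.1% of these changes, and for Ctl-Rz against Ctl-Veh 4.12%, 42.9% and 98.8%. Blocking on the run, it recovered 21.8% of 1.5-fold and 61.8% of 2-fold changes between Ir-Veh and Ctl-Veh, 23.5% and 68.2% for Ir-Rz against Ir-Veh, and 31.2% and 78.8% for Ctl-Rz against Ctl-Veh. Camera called the 8 immediate early genes, shifted together 2-fold in simulated data without run noise, in 10 of 10 sets for each of these comparisons. With no change simulated it called that list in 1 of 10 sets, and 2 of 60 other list tests, for Ir-Veh against Ctl-Veh, and none for RZ in irradiated or in control mice. The simulated genes varied independently, so these rates do not hold where list members vary together. Across the 56 possible splits of the real Ctl-Rz and Ctl-Veh samples, 14 called a list over all cells. In CA1, 6 of the 56, the real one among them, called immediate early genes.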

Results

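Transcripts of 255 genes were counted in 13602 cells annotated as hippocampal neurons on sections from 14 samples. The samples fell into Ctl-Veh (n = 5), Ctl-Rz (n = 3), Ir-Veh (n = 4) and Ir-Rz (n = 2), and each imaging run held 2 samples. Total counts were 274271, 235173, 413159, 247548 and 289391 in Ctl-Veh 2, 3, 8, 11 and 12, where the number is that of the run. They were 249977, 159656 and 279095 in Ctl-Rz 3, 8 and 11, and 255040, 333853, 226516 and 194582 in Ir-Veh 1, 2, 9 and 12. Ir-Rz 1 had 434127 counts in 1449 cells, and Ir-Rz 9 had 137786 counts in 413 cells, the highest and lowest numbers of cells among the 14 samples. The median cell had 239 counts of these genes, with a range of 7 to 985.

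The deposited annotation divided the cells into 8561 dentate gyrus neurons (DG_ExN), 3397 CA1 neurons (CA1_ExN) and 1644 CA3 neurons (CA3_ExN). Fibcd1, a marker of CA1 pyramidal neurons, averaged 6.44 ± 1.56 counts per cell in CA1 (SD, n = 14 samples), against 0.294 in DG and 0.131 in CA3. Iyd, a CA3 marker, averaged 1.14 ± 0.390 counts per CA3 cell, against 0.186 in DG and 0.120 in CA1. Grm2, a presynaptic glutamate receptor of granule cells, averaged 3.09 ± 1.01 counts per DG cell, against 0.116 in CA1 and 0.179 in CA3. Arc, which encodes a cytoskeletal protein of active synapses, averaged 6.05 ± 2.43 counts per cell in CA1, 2.89 ± 1.12 in CA3 and 0.330 ± 0.182 in DG. Egr1, a transcription factor induced by activity, averaged 6.58 ± 1.94 counts per CA1 cell and 0.526 per DG cell. Bdnf, the neurotrophin named in the series title, averaged 0.968 ± 0.314 counts per cell in DG, 0.951 ± 0.448 in CA3 and 0.617 ± 0.246 in CA1.

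The 9 deposited Leiden clusters followed the classes in part. Cluster 0 held 6033 cells, 6000 of them DG, and was richest in Grm2, Adarb2 and Gad1, of which the last pair are inhibitory neuron markers. The other measured markers of that list, Gad2, Cnr1, Erbb4, Crh and Chodl, were lower per DG cell than per CA1 or CA3 cell. Gad2, for example, averaged 0.107 in DG, 0.143 in CA1 and 0.219 in CA3. These levels were not scaled to the counts of a cell. The median cell had 248 counts in cluster 0, 385 in cluster 1 and 374.5 in cluster 8, so the lower levels in DG may come in part from depth. Cluster 1 (3257 cells, 2973 of them CA1) was richest in Adgrl2, Gm2115 and Fibcd1, and cluster 8 (1202 cells, 1129 of them CA3) in Cckbr and Iyd. Cluster 3 mixed 2383 DG, 366 CA1 and 299 CA3 cells, with a median of 96 counts per cell against 248 in cluster 0. The other 5 clusters held 62 cells, among them 24 cells rich in the astrocyte genes Gja1, Aqp4 and Agt and 10 cells rich in the microglial genes Csf1r and Cx3cr1.

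Samples resembled their run partner more than their group. Kcnh7, a potassium channel, differed between runs given the group (edgeR adjusted p = 0.000154), as did 108 of 255 genes in all, among them the glutamate receptor Gria2, the kinase Camk2a and App. Of the 14 samples, 12 were most similar to the sample of the same run. No gene differed between the 4 groups given the run (0 of 255 in edgeR). Values are therefore also given within runs for the main results where a run held both groups. Of the genes named by rule below, Bdnf, Gfap, Arc, Crhr1, Dbh, Crtac1 and Bcl6 (7 genes) had 0.2 or more counts per cell over all cells, and the other 33 lay below that level, near which background counts weigh most.

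**Figure D1:**
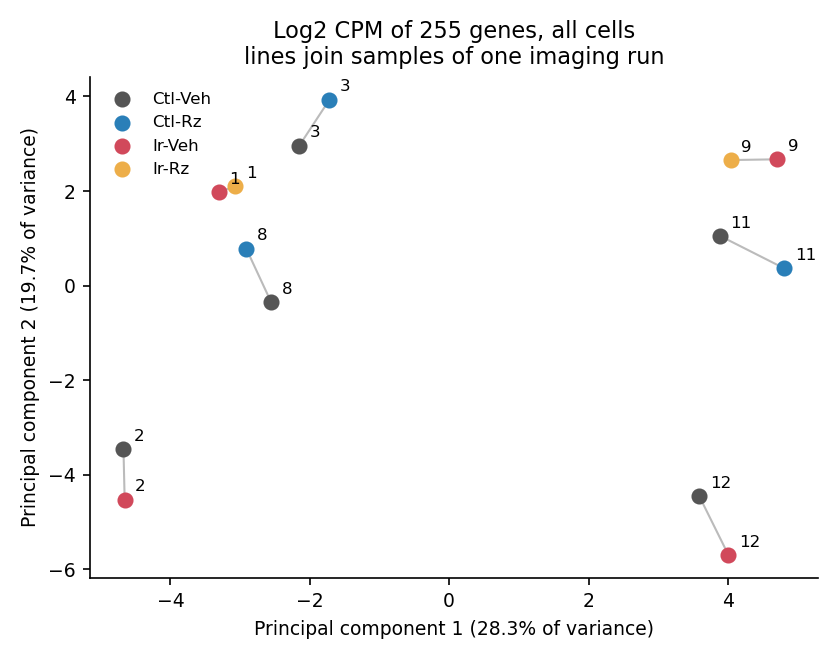
Scores of the 14 samples on the first and second principal components of log2 CPM of 255 genes (28.3% and 19.7% of the variance), coloured by group, with a line joining the 2 samples of each imaging run. Of the 14 samples, 12 were most similar to their run partner over all genes.

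The comparison of Ir-Veh with Ctl-Veh asked what radiation did to these neurons. Bdnf stood at 2469 ± 338 CPM in Ir-Veh (SD, n = 4) and 3268 ± 522 CPM in Ctl-Veh (n = 5), a log2 fold change of −0.40 ± 0.25 (95% interval −0.92 to 0.12) that did not pass the edgeR test. Within run 2 Bdnf was 2431 CPM in the irradiated and 2461 in the control sample, and within run 12 it was 2086 and 3296. Cx3cr1, the fractalkine receptor of microglia, stood at 281 ± 110 CPM in Ir-Veh and 176 ± 39.3 in Ctl-Veh (log2 0.67 ± 0.29), and Drd1, a dopamine receptor, at 487 ± 155 and 742 ± 145 (log2 −0.60 ± 0.28). Gfap, the astrocyte filament gene, differed by log2 0.13 ± 0.28, Arc by −0.12 ± 0.32, and Dcx, a marker of young neurons, by 0.11 ± 0.34. With the run as a block the Arc and Dcx differences took the opposite sign (0.099 and −0.061).

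In edgeR 0 of 255 genes passed between Ir-Veh and Ctl-Veh, the smallest adjusted p was 0.984, and 4 genes had an unadjusted p under 0.05. These were Chodl (0.76 ± 0.30; 137 ± 35.4 against 80.3 ± 25.95 CPM), Cx3cr1, the apolipoprotein gene Apoc1 (0.58 ± 0.27) and Drd1. The next smallest p-values belonged to the cathepsin gene Ctss (−0.66 ± 0.32), the complement gene C3 (−0.70 ± 0.36, and −0.20 without Ctl-Veh 3), Fst (−0.63 ± 0.33), Gbx2 (−0.53 ± 0.28), Degs2 (−0.62 ± 0.33) and the chemokine receptor gene Ccr6 (0.58 ± 0.32). DESeq2 also passed 0 genes, and so did the fits with the run as a block (14 genes at an unadjusted p under 0.05) or as a random effect (15). Within classes edgeR passed 0 of 252 genes in DG, 0 of 233 in CA1 and 0 of 218 in CA3, with 4, 5 and 4 genes at an unadjusted p under 0.05, and DESeq2 passed 0. Bdnf differed by log2 −0.35 in DG, −0.25 in CA1 and −0.44 in CA3.

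No gene list moved between Ir-Veh and Ctl-Veh (0 of 7 by camera, with the preset or an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. Inflammatory signalling (Il1b, Ccl3, Ccl4, Cxcl10, Il10) had 4 of 5 members higher in Ir-Veh, with a median log2 fold change of 0.18 (limma camera adjusted p = 0.540). Complement (C1qa, C3, C4b, Itgam, Itgax) also had 4 of 5 members higher, with a median of 0.18 (adjusted p = 0.604), C3 being the lower member. Per CA1 cell only Il10 (0.265) among the members of both lists exceeded 0.2 counts, with Il1b at 0.0271, C1qa at 0.0421 and Itgam at 0.0330. All cells were annotated as neurons, and the simulated list shift covered immediate early genes only. In each comparison an unmoved inflammatory or complement list is therefore weak evidence of no change. Of the 17 activated microglia genes 9 were higher (median 0.037, adjusted p = 0.925), and of the 8 immediate early genes 4 were (median −0.0091, mean 0.0044, test direction up, adjusted p = 0.925). The synapse list (median 0.035, test direction down), the inhibitory neuron markers (median −0.10) and the neurodegeneration-linked genes (median −0.0083) had an adjusted p of 0.925 as well. In simulated data with 50 of the 255 genes changed at once, 62.9% of 2-fold and 8.24% of 1.5-fold changes between these groups were recovered. With the run as a block these rates were 61.8% and 21.8%. Most differences near 1.5-fold were therefore not detectable here. Recovery of a gene changed alone was not simulated, so the rates do not hold for it.

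**Figure D2:**
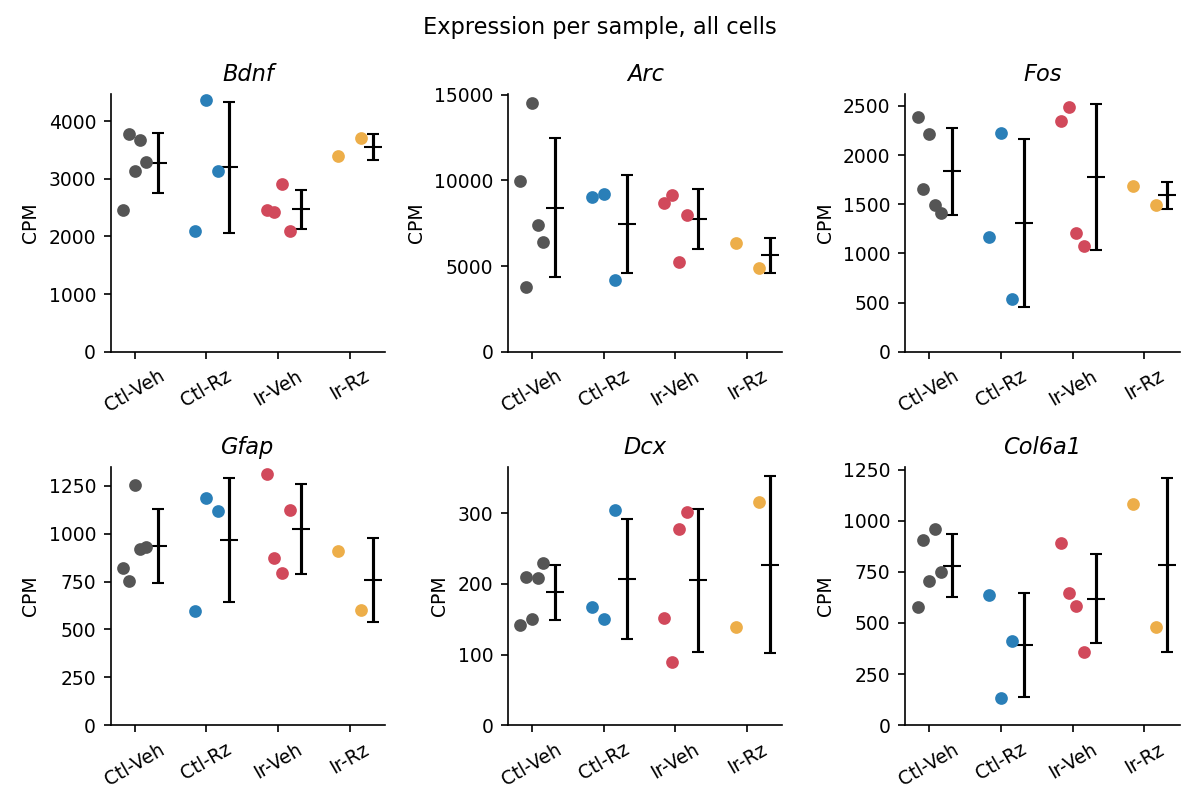
CPM of Bdnf, Arc, Fos, Gfap, Dcx and Col6a1 over all cells of each sample (points), with the mean (dash) and SD (error bar) of the 4 groups. Both Ir-Rz samples lie above the 4 Ir-Veh samples for Bdnf, and Col6a1 averaged 393 CPM in Ctl-Rz and 779 in Ctl-Veh.

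Neurons of CA3 made up 16.3% ± 4.51 of the cells in Ir-Veh (SD, n = 4) and 9.24% ± 3.82 in Ctl-Veh (n = 5), and neurons of DG 56.6% ± 8.16 and 66.4% ± 5.08. Neither share passed the test (exact permutation p = 0.0556 for CA3 and 0.0714 for DG, adjusted p = 0.107 for both). The CA3 share was above the Ctl-Veh mean in 4 of 4 Ir-Veh samples, and within runs 2 and 12 Ir-Veh minus Ctl-Veh was 2.51 and 6.53 percentage points. The DG difference was −19.5 points in 1 of these runs and 1.62 in the other. CA1 neurons made up 27.1% ± 3.98 in Ir-Veh and 24.4% ± 6.34 in Ctl-Veh (exact permutation p = 0.492). By Leiden cluster, cluster 8 held 11.01% ± 2.67 of the cells in Ir-Veh and 7.51% ± 3.21 in Ctl-Veh (exact permutation p = 0.135), cluster 0 held 39.2% ± 10.6 and 47.0% ± 4.61 (exact p = 0.198), cluster 1 held 27.1% and 22.6% (exact p = 0.325), and cluster 3 held 22.1% and 22.3% (exact p = 0.960). An edgeR test on cell numbers gave CA3 a log2 difference of 0.82 with an adjusted p of 0.0777.

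RZ was compared with vehicle on class shares in both irradiated and control mice. CA3 neurons made up 16.95% ± 9.92 in Ir-Rz (n = 2, exact permutation p = 1 against Ir-Veh), DG neurons 58.6% ± 14.8 (exact p = 0.733) and CA1 neurons 24.4% ± 4.85 (exact p = 0.467), in a design whose smallest possible p is 0.0667. Within runs 1 and 9 the CA3 difference was of opposite signs (−6.48 and 5.56 percentage points). In Ctl-Rz (n = 3) CA3 neurons made up 12.6% ± 2.32, above the Ctl-Veh mean in 3 of 3 samples (exact permutation p = 0.179). Within the 3 shared runs the CA3 difference was 1.14 to 7.05 percentage points with a mean of 4.29, higher with RZ in each. The exact permutation p within runs was 0.25, the smallest that 3 runs allow. DG neurons made up 62.9% ± 6.31 there (exact p = 0.446) and CA1 neurons 24.5% ± 4.91 (exact p = 1). The median cell had 244.5 ± 60.6 counts in Ctl-Veh, 262 ± 55.2 in Ctl-Rz, 234 ± 34.3 in Ir-Veh and 284.5 ± 20.5 in Ir-Rz. The exact permutation p was 0.778 for Ir-Veh against Ctl-Veh, 0.2 for Ir-Rz against Ir-Veh and 0.696 for Ctl-Rz against Ctl-Veh.

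**Figure D3:**
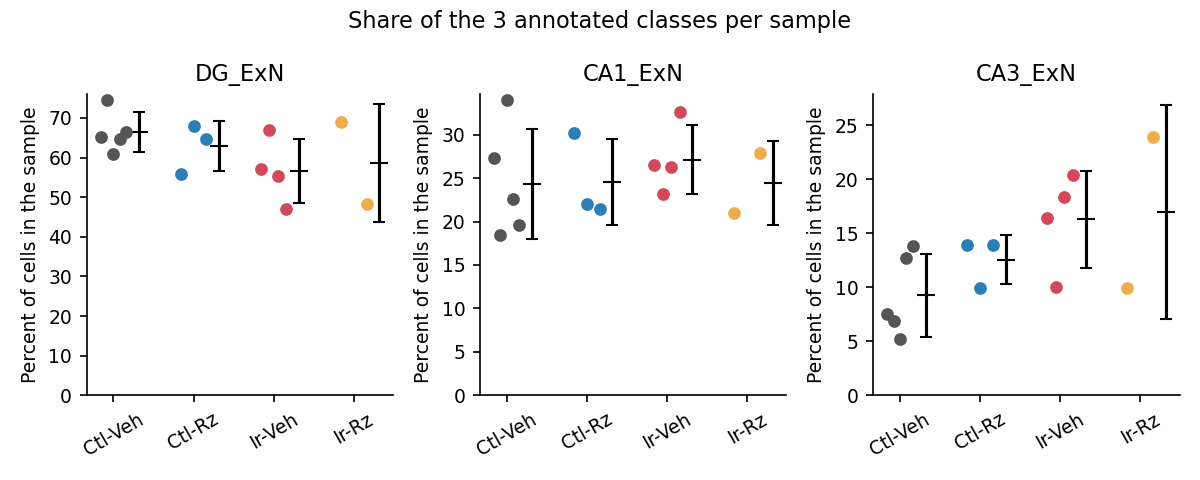
Percent of each sample's cells annotated as DG_ExN, CA1_ExN and CA3_ExN (points), with the mean (dash) and SD (error bar) of the 4 groups. The CA3 share averaged 16.3% in Ir-Veh and 9.24% in Ctl-Veh.

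The comparison of Ir-Rz with Ir-Veh asked what RZ did in irradiated mice. Bdnf stood at 3551 ± 227 CPM in Ir-Rz (SD, n = 2) and 2469 ± 338 CPM in Ir-Veh (n = 4), a log2 fold change of 0.52 ± 0.32 that did not pass the edgeR test. Within run 1 Bdnf was 3391 CPM with RZ and 2451 with vehicle, and within run 9 it was 3712 and 2909. Both Ir-Rz samples lay above all 4 Ir-Veh samples, which ran from 2086 to 2909 CPM. The Bdnf difference was log2 0.41 ± 0.30 in DG, 0.67 ± 0.35 in CA1 and 0.74 ± 0.45 in CA3. Crhr1, a receptor of the stress hormone CRH, stood at 1428 ± 2.99 CPM in Ir-Rz and 2357 ± 617 in Ir-Veh (log2 −0.72 ± 0.34), and the chemokine receptor gene Cxcr4 at 103 and 182 CPM (log2 −0.84 ± 0.36).

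In edgeR 0 of 255 genes passed between Ir-Rz and Ir-Veh (smallest adjusted p = 0.990), and only Cxcr4 and Crhr1 had an unadjusted p under 0.05 (2 genes). Beside these and Bdnf, the smallest p-values belonged to the connexin gene Gjc1 (0.87 ± 0.42), Gng8 (−0.99 ± 0.51), the interneuron transcription factor gene Dlx2 (0.69 ± 0.36), the cathepsin gene Ctsc (0.63 ± 0.34), Dbh, which makes noradrenaline (−0.98 ± 0.57, and 0.13 with the run as a block), the integrin gene Itgal (0.81 ± 0.47) and Epha1 (−0.64 ± 0.39). Gfap differed by log2 −0.43 ± 0.37, Arc by −0.46 ± 0.42 and Dcx by 0.12 ± 0.45. DESeq2 and the fits with the run as a block (1 gene at an unadjusted p under 0.05) or as a random effect (5) passed 0 genes. Within classes edgeR and DESeq2 passed 0 genes, with 5 genes in DG, 3 in CA1 and 4 in CA3 at an unadjusted p under 0.05 in edgeR.

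Arc in DG neurons had a log2 fold change of −1.55 ± 0.51 between Ir-Rz and Ir-Veh (edgeR adjusted p = 0.997), and was singled out after its values were seen. Within run 1 it was 601 CPM with RZ and 2824 with vehicle, and within run 9 it was 493 and 865. Cbln4, a synaptic organizer, differed by log2 2.14 ± 0.62 in CA3 (adjusted p = 0.498), also chosen after its values were seen; without Ir-Rz 9 it was 2.92 with an adjusted p of 0.0358, and the remaining Ir-Rz sample was then assumed to vary like the other groups. No list moved (0 of 7 by camera with the preset or an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. Immediate early genes had 2 of 8 members higher (median −0.23) and complement 1 of 5 (median −0.18). Activated microglia had a median of −0.044 (7 of 17 higher) and inhibitory neuron markers 0.083 (4 of 7 higher). Median, mean and test differed in sign for inflammatory signalling (median 0.0032, mean −0.048, test direction down), neurodegeneration-linked genes (median 0.056, mean −0.069, down) and synapse genes (median −0.036, mean 0.0085, down). The camera adjusted p was 0.745 for each of the 7 lists. In simulated data with 50 genes changed at once, 26.5% of 2-fold changes were recovered in this comparison, or 68.2% with the run as a block.

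The comparison of Ctl-Rz with Ctl-Veh asked what RZ did without radiation. Col6a1, a collagen gene, stood at 393 ± 253 CPM in Ctl-Rz (SD, n = 3) and 779 ± 154 in Ctl-Veh (n = 5), a log2 fold change of −0.97 ± 0.41 (95% interval −1.81 to −0.13; edgeR adjusted p = 0.989). It was lower with RZ in each shared run, at 637 against 905 CPM in run 3, 131 against 704 in run 8 and 411 against 959 in run 11. With the run as a random effect, a fit chosen after the data had been seen, Col6a1 fell by 1.33 ± 0.28 (limma adjusted p = 0.0158); with the run as a block the value was −1.26 ± 0.32 (edgeR adjusted p = 0.367). Without Ctl-Rz 8 the edgeR value was −0.57. Crtac1, an extracellular matrix protein gene, stood at 3451 ± 1095 CPM in Ctl-Rz and 5811 ± 1883 in Ctl-Veh (log2 −0.75 ± 0.36). Bdnf stood at 3198 ± 1132 CPM in Ctl-Rz, a difference of log2 −0.032 from Ctl-Veh.

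In edgeR 0 of 255 genes passed between Ctl-Rz and Ctl-Veh (smallest adjusted p = 0.989), with 6 genes at an unadjusted p under 0.05. DESeq2 passed 0, the fit with the run as a block passed 0 (16 genes at an unadjusted p under 0.05), and that with the run as a random effect passed 1, Col6a1 (21 genes). The smallest p-values also included the endothelial genes Ecscr (0.89 ± 0.33; 128 against 67.3 CPM) and Flt1 (0.85 ± 0.36, and 0.062 without Ctl-Rz 3), the ependymal gene Ccdc153 (0.85 ± 0.35), the oxygen-sensing enzyme gene Egln3 (0.75 ± 0.32, and 0.29 without Ctl-Rz 3), Hsd11b1, which regenerates glucocorticoid (−0.60 ± 0.29), the NMDA receptor gene Grin2c (0.58 ± 0.28), Abi3 (−0.81 ± 0.40) and Gjc1 (0.67 ± 0.35). Arc differed by log2 −0.17, Dcx by 0.16 and Gfap by 0.047, and Gfap took the opposite sign with the run as a block (−0.036). Within classes edgeR and DESeq2 passed 0 genes, with 4 genes in DG, 2 in CA1 and 6 in CA3 at an unadjusted p under 0.05 in edgeR. In DG the random-effect fit passed 2 genes, Adgrg7, which fell by 1.75 ± 0.43, and Col6a1, which fell by 1.38 (limma adjusted p = 0.0469 for both). Adgrg7 averaged 0.0199 counts per DG cell, far below the 0.2 taken as a minimum above, and with the run as a block neither passed (−1.59 ± 0.42 for Adgrg7 and −1.29 ± 0.40 for Col6a1, edgeR adjusted p = 0.737 for both).

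Over all cells no list moved between Ctl-Rz and Ctl-Veh (0 of 7 by camera, with the preset or an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. Immediate early genes had 2 of 8 members higher (median −0.16, camera adjusted p = 0.358); without Ctl-Rz 8 the adjusted p was 0.00484, and without Ctl-Veh 12 it was 0.0452. Inflammatory signalling had 5 of 5 members higher (median 0.14, adjusted p = 0.372), and neurodegeneration-linked genes 1 of 5 (median −0.25, adjusted p = 0.358). Synapse genes had 5 of 17 members higher (median −0.092, adjusted p = 0.413), activated microglia 10 of 17 (median 0.043, adjusted p = 0.588) and inhibitory neuron markers 4 of 7 (median 0.066, adjusted p = 0.604). Complement had 3 of 5 (median 0.13, mean −0.0060, test direction up, adjusted p = 0.604).

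Within CA1, immediate early genes were lower in Ctl-Rz than in Ctl-Veh, a test chosen after the data had been seen. Of the 8 members 2 were higher (Homer1 0.29, Egr4 0.12), and Egr2 (−0.78 ± 0.31), Fosb (−0.69), Fos (−0.52), Fosl2 (−0.33), Arc (−0.13) and Egr1 (−0.10) were lower, with a median log2 fold change of −0.23. Camera gave an adjusted p of 0.0123 over the 7 lists, but p = 0.0611 with an estimated correlation (adjusted p = 0.428) and an adjusted p of 0.1002 over the 57 list tests within classes of Ir-Veh and Ctl-Rz against Ctl-Veh and of Ir-Rz against Ir-Veh. The mean log2 level of the list against other genes was 1.23 ± 0.404 in Ctl-Rz (n = 3) and 1.55 ± 0.101 in Ctl-Veh (n = 5), with an exact permutation p of 0.0893. It was lower with RZ in each of the 3 shared runs, with differences from −0.719 to −0.0516, but 1 sample carried most of it. Without Ctl-Rz 11 the difference was −0.0921 in place of −0.313, and the camera adjusted p was 0.770, or 0.852 with the run as a block, where leaving out Ctl-Veh 11 gave 0.892. Without Ctl-Veh 8 the camera adjusted p was 0.128. Leaving out Ctl-Rz 8 went the other way, to a difference of −0.488 (exact permutation p = 0.0476, camera adjusted p = 9.87e-05, and p = 0.0129 with an estimated correlation), and without Ctl-Veh 12 the estimated correlation gave p = 0.0485 (camera adjusted p = 0.00467). The difference of this list's RZ effects between irradiated and control mice in CA1 had a camera adjusted p of 0.0718, or 0.0297 with the run as a block (p = 0.172 with the block and an estimated correlation).

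The comparison of Ir-Rz with Ctl-Veh set the irradiated and treated mice against untreated controls, and no run held both groups. Bdnf differed by log2 0.12 ± 0.31, Gfap by −0.30, Arc by −0.58 ± 0.41 and Dcx by 0.23, none past the edgeR test. The transcriptional repressor gene Bcl6 stood at 3540 CPM in Ir-Rz (n = 2) and 5615 in Ctl-Veh (n = 5), a log2 fold change of −0.67. In DG neurons Arc differed by −1.71 ± 0.50 (edgeR adjusted p = 0.592), a value singled out after it was seen. In edgeR 0 of 255 genes passed (smallest adjusted p = 0.992), with 1 gene, Ctsc (0.79), at an unadjusted p under 0.05, and DESeq2 and both fits with the run passed 0. The smallest p-values also included Gm11627 (−0.78 ± 0.41), the T cell gene Cd8a (0.74 ± 0.39), the proteoglycan gene Dcn (−0.88 ± 0.48), Csf1r, the microglial survival receptor (−0.62 ± 0.35), the choroid plexus gene Clic6 (0.70), Cxcr4 (−0.57), Gng8 (−0.76) and Abi3 (−0.71). Dcn and Cxcr4 took the opposite sign with the run as a block (0.39 and 0.11), as did Dcx (−0.023). Within classes edgeR passed 0 genes, with 5 genes in DG, 3 in CA1 and 1 in CA3 at an unadjusted p under 0.05. In DG the immediate early genes were lower in Ir-Rz by camera (adjusted p = 0.0341), but not with the run as a block (adjusted p = 0.131) or an estimated correlation (p = 0.180). The synapse genes in DG had an adjusted p of 0.977, and 0.0342 with the run as a block, in the direction of higher in Ir-Rz (median −0.053 and mean 0.043 without the block, adjusted p = 0.268 with the block and an estimated correlation). List tests within classes were chosen after the data had been seen.

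The difference between the RZ effect in irradiated and in control mice was tested as an interaction. For Bdnf it was log2 0.56 ± 0.42, for Gfap −0.48, for Arc −0.29 and for Dcx −0.041, none past the edgeR test. Col6a1 (1.31 ± 0.60, and 0.61 without Ir-Rz 1), Dlx2 (1.06 ± 0.48) and Flt1, the endothelial VEGF receptor gene (−1.22 ± 0.58, and −0.43 without Ctl-Rz 3), were the 3 genes with an unadjusted p under 0.05, and 0 of 255 genes passed (edgeR smallest adjusted p = 0.998). The next were Apoc1 (−0.93 ± 0.46), Epha1 (−0.90 ± 0.50), Ccdc153 (−0.92 ± 0.56), the gut peptide receptor gene Glp2r (−0.66), Gng8 (−0.93), the angiotensinogen gene Agt (0.63) and Grin2c (−0.62). DESeq2 and both fits with the run passed 0 genes. Within classes edgeR passed 0 genes, with 0 in DG, 0 in CA1 and 3 in CA3 at an unadjusted p under 0.05. Synapse genes in DG had 13 of 17 members with a positive difference (median 0.10) and a camera adjusted p of 0.675. This was 0.0246 with the run as a block, and 0.240 with the block and an estimated correlation.

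The series title speaks of reversal of radiation effects, so the RZ effect in irradiated mice was set against the radiation effect across genes. Bdnf had opposite signs in them (log2 −0.40 with radiation and 0.52 with RZ). Across the 255 genes, which are not independent replicates, the correlation was −0.419 and the covariance −0.0314. The shared Ir-Veh samples give a negative correlation without any effect. In simulated groups without effects the mean correlation was −0.406 (95% range −0.884 to 0.404) with independent samples and −0.0695 (−0.782 to 0.708) with noise shared within runs. With the 4 Ir-Veh samples split so that none entered both effects, the 6 correlations were 0.294, 0.462, −0.0709, 0.0792, −0.121 and 0.365. Ir-Veh 1 and 9 shared runs with Ir-Rz 1 and 9, so noise of a run could still enter both effects. The correlation was 0.462 with both of these samples in the radiation effect and −0.121 with neither. No splits without effects were simulated, so these values do not decide for or against reversal. The observed correlation lay within the simulated range, so no reversal beyond the shared samples was detectable. Without Ir-Rz 1 the correlation was −0.0793.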

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

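The tests of the first pattern below and all but 1 of those of the second were chosen only after the result was seen, as were the counts over other splits; the test of the list score in CA1 was written before. Of 88 groups of samples examined over the named values, 5 held a sample far from the others, and chance gives about 1 in 20 groups, or 5%. Apoc1 stood at 343 CPM in Ir-Veh 2, with the other Ir-Veh samples at 188 to 200 CPM. C3 stood at 845 CPM in Ctl-Veh 3, with the others at 187 to 301. Ccr6 stood at 120 CPM in Ctl-Veh 8, with the others at 49.0 to 64.7. Gjc1 stood at 34.9 CPM in Ir-Veh 12, with the others at 60.6 to 65.9, and Agt at 146 CPM in Ir-Veh 9, with the others at 102 to 105.

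Samples of the same imaging run deviated together from their group means, with a median correlation of 0.515 over the 7 runs and −0.170 between samples of different runs. Subtracting group means pushes samples of the same group, all in different runs, towards negative correlations (−1 for Ir-Rz 1 and 9). The −0.170 is therefore low in part by construction. With counts per cell as a covariate the same-run median was 0.544, and among genes with 0.2 or more counts per cell it was 0.713 (lowest run 0.133), which argues against depth and against background counts as the whole source. Within DG cells alone it was 0.417, which argues against the shares of the 3 classes as the whole source, although it fell to 0.215 (lowest run −0.00848) with class shares as covariates, so these may account for part. What else the samples of a run have in common, such as reagents or section position, stays open. No biological explanation was tested, because each run held 2 groups.

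Immediate early genes were lower in CA1 of Ctl-Rz than of Ctl-Veh by camera with its preset correlation (median log2 −0.23, lower in 6 of 8 members). With the run as a block the camera p was 0.00128, the mean difference of the list's level within runs was −0.313, and Ctl-Veh 11 stood at 1.51 beside 0.792 in Ctl-Rz 11, which argues against a shift shared by both samples of a run. With an estimated correlation the p was 0.0611, or 0.134 with the block, so members that vary together between sections remain a candidate explanation, and the blocked call rests on run 11 (adjusted p 0.852 without Ctl-Rz 11 and 0.892 without Ctl-Veh 11). An effect of RZ and a deviation of Ctl-Rz 11 alone cannot be told apart, because the exact permutation test of the list's level gave p = 0.0893 with 3 and 5 samples and the difference was −0.0921 in place of −0.313 without that sample. Over the 56 splits of these samples, 4 gave an adjusted p as small as the real 0.0123, and the lowest of the others was 0.00368, so chance cannot be excluded.

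For Ir-Veh against Ctl-Veh, 100 of the 126 possible splits of the 9 samples were drawn. The real split gave 0 genes, 0 gene and class pairs and 0 lists, so that 100, 100 and 100 of 100 splits gave as many by construction, which says nothing about chance. The highest counts in other splits were 27 genes, 41 pairs and 1 list. The split with 27 genes set Ir-Veh 9, Ctl-Veh 11, Ctl-Veh 12 and Ir-Veh 12 against the rest and so kept both samples of run 12, and both of run 2, on the same side, which points to a structure of the samples by run. It also set runs 9, 11 and 12 against runs 1, 2, 3 and 8. The first principal component parted these runs as well, with scores of 3.59 to 4.81 against −4.67 to −1.72. Like the real split, 33 of the 100 parted the samples of both runs, and the others among them gave at most 0 genes, 0 pairs and 1 list. With the run as a block the real split gave 0 genes. For Ctl-Rz against Ctl-Veh, 56, 56 and 56 of all 56 splits gave as many genes, pairs and lists as the real 0, which again follows from a count of 0, with highest other counts of 5, 8 and 1. Of these, 8 splits parted the samples of all 3 shared runs as the real one did, and the other 7 gave 0 genes, 0 pairs and 0 lists. For the immediate early genes in CA1, the lowest adjusted p of those 7 was 0.0670, and 8 splits are too few for a share under 0.05.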

How the results depend on the processing

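Tests with the run as a random effect, deposited totals, genes above background or without run 9 and list tests within classes were chosen only after the result was seen. No gene, no pair and no list over all cells was called between groups in the planned tests, and the counts of 0 in edgeR, DESeq2 and the other planned settings stayed at 0 outside the exceptions below. The replicate block changed no call of genes, pairs or lists over all cells. For shares it could give no call, because the test within 2 or 3 shared runs cannot reach a p under 0.5 or 0.25. Among 95 list tests within classes 2 were called, 4 with the block, and the block changed 4 calls: in DG, immediate early genes (adjusted p 0.0341 to 0.131) and synapse genes (0.977 to 0.0342) for Ir-Rz against Ctl-Veh and synapse genes for the difference of RZ effects (0.675 to 0.0246), and in CA1, immediate early genes for that difference (0.0718 to 0.0297). With an estimated correlation 0 of the 95 were called, with or without the block. Over planned settings, values of named genes kept their direction and side of the threshold in 1044 cases and reversed in 35, class shares in 75 and 12, and other results in 230, with 10 moved and 4 reversed. Over settings added later, named genes kept them in 202 cases, with 9 reversed and 1 newly past the threshold (Col6a1), class shares in 9, and other results in 39, with 2 moved and 1 newly past the threshold (the level of immediate early genes in CA1 without Ctl-Rz 8). A pseudocount for values that are not counts was not run, because the values are counts. In simulated data at these depths the block raised the recovery of 1.5-fold changes from 4.12% to 31.2% for Ctl-Rz and from 2.35% to 23.5% for Ir-Rz against Ir-Veh, so run variation sets part of the limit; how far depth limits the 161 genes with under 0.2 counts per cell was not tested.

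The number of cells as library size moved the median log2 fold change of all genes to 0.35 for Ir-Rz against Ir-Veh, 0.23 for Ctl-Rz against Ctl-Veh, 0.39 for Ir-Rz against Ctl-Veh and 0.12 for the difference of RZ effects; library size alone moved it to 0.13 (Ctl-Rz) and 0.14 (Ir-Rz against Ctl-Veh), and deposited totals to 0.14 and 0.13. Bdnf in Ctl-Rz against Ctl-Veh reversed to 0.073 with library size alone, 0.15 with the number of cells, 0.079 with deposited totals and 0.029 with genes above background. With the number of cells the difference of RZ effects reversed to 0.12 for Dcx and 0.025 for Arc. The cause was not tested for these or the reversals that follow.

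With the replicate block, Dcx (−0.061) and Arc (0.099) reversed for radiation, Dbh (0.13) for RZ in irradiated mice, Gfap (−0.036) for RZ in controls, and Dcx (−0.023), Dcn (0.39) and Cxcr4 (0.11) for Ir-Rz against Ctl-Veh. The CA3 share of Ir-Rz minus Ir-Veh became −0.462 percentage points, the CA1 share of Ctl-Rz minus Ctl-Veh −0.453 points, and the difference in median counts per cell of Ctl-Rz −2.33. With the run as a random effect the values were −0.079 for Dcx and 0.022 for Arc under radiation, −0.028 for Gfap in Ctl-Rz and −0.013 for Dcx in Ir-Rz against Ctl-Veh, and Ctl-Rz against Ctl-Veh gave 1 gene and 2 pairs in place of 0 and 0. Without run 9 Dcx was −0.14 for radiation, −0.31 for RZ in irradiated mice and −0.44 for Ir-Rz against Ctl-Veh.

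Leaving out each sample in turn, Dcx ran from −0.12 to 0.37 for radiation, −0.55 to 0.63 for RZ in irradiated mice, −0.24 to 0.33 for RZ in controls, −0.44 to 0.75 for Ir-Rz against Ctl-Veh and −0.71 to 0.48 for the difference of RZ effects. Gfap ran from −0.0099 to 0.26 for radiation and −0.12 to 0.30 in Ctl-Rz, Arc from −0.37 to 0.17 and −0.38 to 0.12, and Bdnf in Ctl-Rz from −0.32 to 0.20. The level of immediate early genes in CA1 of Ctl-Rz minus Ctl-Veh ran from −0.488 to −0.0921. Of 69 values of named genes 10 took the opposite sign without some sample and 29 others moved by over 1.5 times, as did 5 and 1 of 9 class shares. Gfap ran from −0.77 to −0.17 for RZ in irradiated mice and −0.64 to −0.038 for Ir-Rz against Ctl-Veh, Abi3 in Ctl-Rz from −1.38 to −0.44, Apoc1 for radiation from 0.33 to 0.67, Cd8a and Cxcr4 for Ir-Rz against Ctl-Veh from 0.41 to 1.06 and −0.79 to −0.33, and the CA1 share for radiation from 0.908 to 5.14 points. A single sample moved Clic6 for Ir-Rz against Ctl-Veh to 0.16 and Itgal for RZ in irradiated mice to 0.20 (both without Ir-Rz 1), and Dbh to −0.46 (without Ir-Veh 2). Pairs for RZ in irradiated mice ran from 0 to 1 (Cbln4 in CA3 without Ir-Rz 9) and lists in Ctl-Rz from 0 to 1 (immediate early genes without Ctl-Rz 8 or Ctl-Veh 12). The correlation of the RZ with the radiation effect ran from −0.654 to −0.0793, and with Ir-Veh split it was 0.294, 0.462, −0.0709, 0.0792, −0.121 and 0.365. Differences in shares for RZ in irradiated mice ran from −8.39 to 12.5 points for DG, −6.14 to 0.727 for CA1 and −6.37 to 7.66 for CA3, and in Ctl-Rz from −6.10 to 0.00975 for DG and −2.66 to 2.56 for CA1. The difference in median counts per cell ran from −25.1 to 12.75 for radiation and −14.5 to 40.4 in Ctl-Rz. Where 1 Ir-Rz sample was left, it was assumed to vary like the other groups.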

Other observations

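The tests on Arc-rich cells were chosen after the classes had been seen; those of Fos and Cckbr within Leiden cluster 0 were written before their results were seen. In each section and class, the 10% of cells with the largest share of Arc among their counts were compared with the rest, with Arc itself left out and the section as a block in edgeR; no other percentage was run. In DG, Fos was higher in these cells by log2 3.87 ± 0.21 (14 of 14 sections, adjusted p = 2.63e-16), with Fosb (2.86 ± 0.19), Egr2 (2.57), Egr1 (2.13), Egr4 (1.52) and Fosl2 (1.24), all transcription factors induced by neuronal activity. The stress-responsive factor Atf3 (1.90 ± 0.22) and Acan, a component of perineuronal nets (1.04), were higher too. Bdnf, an activity-regulated neurotrophin, was higher by 0.52 ± 0.08 (13 of 14 sections, adjusted p = 1.54e-06), at 0.054 ± 0.19 in Ir-Rz, 0.69 in Ir-Veh, 0.53 in Ctl-Veh and 0.60 in Ctl-Rz. Lower were the AMPA receptor partner Cacng5 (−0.91), the calcium buffer Calb1 (−0.77), Bcl11b (−0.50) and Grm2 (−0.35). Per DG cell, Egr2, Atf3, Calb1, Cacng5, Egr4, Fosb and Acan lay below 0.2 counts (0.065 to 0.189). Fos, Egr1, Fosl2, Bdnf, Bcl11b and Grm2 lay above that level. In all 27 genes were higher and 37 lower of 153 tested, against 0 and 1 of 144 with randomly drawn cells. The random draw was not matched on counts per cell. The chosen DG cells had the higher median in most sections (345 against 275 in Ctl-Rz 11), but not in Ctl-Veh 8 (221 against 254) or Ctl-Veh 11. Of the 27, 21 could be tested within cluster 0, the main cluster of the DG class, where 16 were higher and Dkk3 and Cck were lower (2 genes). Of the 37, 36 could be tested there, and 19 were lower.

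In CA1, Fos (2.96), Egr2 (2.88), Fosb (2.87), Fosl2 (1.63) and Egr1 (1.24) were higher in the Arc-rich cells, as were Chrm4 (0.65), the adrenergic receptor gene Adrb1 (0.51) and Bdnf (0.43 ± 0.13; 10 of 14 sections, adjusted p = 0.0168). Lower there were Adam17 (−0.73), Crtac1 (−0.65), Camk2g (−0.59) and Fibcd1 (−0.20), and 10 genes were higher and 16 lower of 120. In CA3, Fos (4.19), Egr4 (2.38), Fosl2 (2.11), Chrm4 (0.98) and Bdnf (0.61 ± 0.14; 12 of 14 sections, adjusted p = 0.00182) were higher and Dapk1 (−0.36) was lower, with 7 genes higher and 4 lower of 78.

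The choice by share was less strict where Arc was scarce. In Ir-Rz 1 and 9 the Arc-rich DG cells averaged 1.37 and 1.5 Arc counts, against 1.90 to 6.45 in the other sections. Of these cells 40 of 100 and 6 of 20 held none. Cells without Arc were also chosen in Ctl-Veh 3 (26 of 82), Ir-Veh 2 (25 of 92), Ctl-Veh 2 (21 of 87), Ctl-Veh 12 (13 of 73) and Ctl-Rz 11 (1 of 52). The unlike selection may give part of the smaller differences in DG of Ir-Rz. In cluster 0 the averages were 1.08 and 1 in Ir-Rz, against 1.32 to 3.24. With only those of the chosen cells that held Arc, 28 genes were higher and 34 lower of 139 in DG, Fos by 4.07 ± 0.22 and Bdnf by 0.59 ± 0.07 (14 of 14 sections). In DG of Ir-Rz, Bdnf was then 0.18 ± 0.19 against 0.61 to 0.71 in the other groups, and Fos 3.43 ± 0.56 against 3.78 to 4.39. Leaving out the cells without Arc thus did not close the gap for Bdnf. A fit with 1 difference per group, chosen after the group means had been seen, called no gene as varying between the 4 groups (0 of 153 in DG, 0 of 120 in CA1, 0 of 78 in CA3 and 0 of 125 in cluster 0). With the cells that held Arc, chosen later still, it called 0 in the classes and 2 in cluster 0, Fos (0.58 ± 0.55 in Ir-Rz and 1.99 to 2.85 in the other groups, adjusted p = 0.0322) and Egr1 (0.47 ± 0.30 and 0.75 to 1.63, adjusted p = 0.0310). By section, with all chosen cells of cluster 0, Fos was 0.32 in Ir-Rz 1 and 0.85 in Ir-Rz 9. It was as low in Ctl-Rz 8 (0.11) and Ir-Veh 12 (0.20), and 1.22 to 3.34 in all remaining sections. Ir-Rz 9 had 13 chosen cells there, 3 of them without Arc, and 3 Fos counts in them. Bdnf in Ir-Rz (n = 2) was −0.37 ± 0.33 in CA1 and −0.096 ± 0.33 in CA3, against 0.42 to 0.65 and 0.66 to 0.90 in the other groups, and did not pass as set apart from them (edgeR adjusted p = 0.713 and 0.313, and 0.358 in DG). Only Fam107a in CA3 was set apart in Ir-Rz (1.67 ± 0.43, and 1.92 ± 0.49 above the mean of the others, adjusted p = 0.0310).

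Immediate early genes and Cckbr, the cholecystokinin receptor gene that marks CA3 here (0.747 counts per cell, against 0.0465 in DG), were both higher in the Arc-rich DG cells (Cckbr 2.09 ± 0.26, 13 of 14 sections), with Cckbr at −0.65 ± 0.99 in Ir-Rz (with 0 counts in the Arc-rich cells of Ir-Rz 9). CA3 neurons annotated as DG could give part of this, since they carry more Arc. Of 11 other genes abundant in CA3, some still more so in CA1, 7 were higher as well (median 0.43). Dkk3 (0.77) and Chrm4 (1.13, but −0.22 ± 0.63 in Ir-Rz) were both more abundant in CA1 than in CA3. Iyd, the CA3 marker above, was the lowest of the 11 at −0.089. The 5 CA1 genes had a median of −0.25 with an SD of 0.54. Fibcd1 (−0.74 ± 0.14) and Htr1a (−0.57) were called lower, and Gm2115 was called higher (0.57 ± 0.22, edgeR adjusted p = 0.0329). Adgrl2 (−0.25) and Kcnh7 (0.21) were not called. As Fibcd1 was also lower in Arc-rich CA1 cells (−0.20), these genes do not decide about CA1 neurons as a source. Leiden cluster 0 holds 6000 DG cells and has the inhibitory markers Gad1 and Adarb2, but not the other measured ones, among its top genes. Within it Fos was still higher by 2.29 ± 0.20 (14 of 14 sections), which argues against CA neurons as the whole source for immediate early genes. Cckbr, kept past the low-count filter on purpose, was higher there by 0.984 ± 0.356 (9 of 14 sections, edgeR adjusted p = 0.0278). In Ir-Rz it was −1.51 ± 1.27. Cckbr alone did not decide. The 6 other genes abundant in CA3 that were tested in cluster 0 did not share its rise, with a median of −0.16 (−0.34 for Dkk3 to 0.070 for Bcan). Most cells of cluster 8, richest in Cckbr and Iyd, were CA3, so cells high in CA3 genes may already have been placed outside cluster 0. The low values of the 6 genes are therefore only a weak argument against CA3 neurons within cluster 0. The tests of CA1 genes and of these 6 genes were chosen after the result was seen. Joint activity of DG neurons is a hypothesis for the first part, found and tested on the same data.

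In DG, camera gave immediate early genes an adjusted p of 0.0341 for Ir-Rz against Ctl-Veh, lower in Ir-Rz, with 0.880 with an estimated correlation, and an exact permutation p of 0.238 for the list's level (difference −0.410), so this call was not kept. CA3 cells had a median of 397 counts in Ir-Rz (n = 2) and 285.6 in Ir-Veh (n = 4), with an exact permutation p of 0.0667, the smallest this design can give.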
